A study of Homo sapiens with 4 samples.

How the data were processed

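Ribosome-protected fragments (RPF) and total RNA were sequenced from SW480 cells, wild type or labelled as lacking IMP1 (gene symbol IGF2BP1). There were 4 libraries, 1 for each combination of genotype and library kind, and per the labels' protocols each was made from 3 pooled culture plates. Groups were taken from the library titles. The cell-line field of the wild-type RNA library reads SW840, while its source name and the labels of the other libraries read SW480. It was analysed as SW480, and this conflict in the labels was not resolved.

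Per the labels' protocols, footprints of 18 to 34 nt and RNA fragments of 18 to 50 nt were selected, separate linkers with random molecular identifiers of 4 nt at the 5′ end and 5 nt at the 3′ end were ligated, ribosomal RNA was depleted with RiboZero, and libraries were amplified over 15 PCR cycles. The submitters' processing notes name cutadapt 1.10, Bowtie 1.1.2, HISAT2 2.1.0 and the GRCh38 build. The role of each tool, the annotation, the region of each transcript that was counted, the treatment of reads that map to more than 1 gene and any collapsing by molecular identifier are not given in the sources used here. The values the authors deposited are whole-number read counts per gene, not normalized, with 1 Ensembl transcript per gene symbol and the same 19192 genes in the same order in each of the 4 libraries. Of these transcripts, 19176 (99.9%) were found in GENCODE release 29 (Ensembl 94, GRCh38), from which coordinates, GC content and length were taken, and 18315 had the same symbol there.

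Library totals were 3782874 counts for wild-type RPF, 3778316 for knockout-labelled RPF, 5551479 for wild-type RNA and 4932388 for knockout-labelled RNA. A count of 0 allowed a level of up to 3 counts, which was 0.793, 0.794, 0.540 and 0.608 CPM in these libraries. Libraries of 1 kind were scaled together by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. The knockout-labelled to wild-type scaling ratio was 0.900 for RNA and 1.00 for RPF. All other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

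The 3 quantities computed per gene were each a log2 ratio of the knockout-labelled over the wild-type library with a prior count of 0.5: the RNA change, the RPF change, and the change in translational efficiency (TE), which is RPF change minus RNA change. RNA and RPF changes have exact conditional (Clopper-Pearson) 95% intervals of the count ratio, and TE changes have 95% intervals from the sum of reciprocal counts. Counts of reads after PCR are not counts of molecules, so these intervals and the floors cover counting error only. Genes entered a comparison with at least 50 reads over both libraries of a kind, and TE required this of both kinds. A gene was called higher or lower when the ratio was at least 2-fold and the interval excluded no change. Members of gene lists were called at 1.5-fold. The interaction of library kind and genotype has 0 residual degrees of freedom in 4 libraries, so TE change is a value and not a test. With 1 library per group no difference has a replicate check, and no p-value is given. Correlations across genes describe these libraries, since genes are not independent replicates.

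A set of 30 lists was fixed, with the comparisons, thresholds, alternatives and the rule for named genes, before the data were examined. The lists hold the IMP1 family, IMP1 target transcripts, autophagy, lysosome, cytosolic ribosomal proteins, translation factors, the nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, G1/S and replication, G2/M and mitosis, replication-dependent histones, Wnt target and stem cell genes, intestinal differentiation, epithelial adhesion and barrier, interferon response, inflammatory and NF-kB genes, endoplasmic reticulum stress, ATF4 targets and amino acid genes, cholesterol synthesis, glycolysis, hypoxia, heat shock chaperones, immediate early genes, PI3K and mTOR, integrins and matrix, the proteasome, and antioxidant and NRF2 genes. Markers of mesenchymal and fibroblast cells, of leukocytes and endothelium, and of neuronal and other lineages stood for cell types other than epithelium. Some genes are in more than 1 list. The median change of a list was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile is a description of these libraries.

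Named genes are IGF2BP1, IGF2BP2 and IGF2BP3, the top 12 genes on each side of each comparison when ranked by the bound of the 95% interval nearest to no change, up to 4 members of each list per comparison by the same ranking, and fixed members of the autophagy list (ATG3, ATG5, MAP1LC3B, SQSTM1) and of the IMP1 target list (ACTB, CD44, CTNNB1). MYC was not analysed here, and not every gene that this rule names is reported here. Folds against a library with 0 reads are taken against a floor of 3 counts in that library. They leave out the counting error of the other library, so exact 95% bounds can lie nearer to no change. Histone genes, KRT81, KRT83 and KRT86, the KRTAP2 genes, the MTRNR2L genes, RIMBP3 and RIMBP3B, and ribosomal protein and ferritin genes with processed pseudogenes have near-identical copies, so their values are uncertain where the counting split or shared reads.

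The calculation was tested on simulated counts drawn from the means and totals of these libraries with 200 changed genes. For RNA, 99 of 99 genes changed 3-fold and 97 of 97 changed 4-fold were called among 10848 genes, and 3 of 10652 unchanged genes were called. For RPF, 47 of 47 and 49 of 49 were called among 9799 genes, with 5 of 9703 unchanged genes called. For TE, 48 of 49 and 50 of 50 were called among 9578 genes, with 46 of 9479 unchanged genes called. Of 100 simulated lists of unchanged genes 4 lay outside the middle 95%, and a planted list lay at percentile 100. This simulation holds counting error and no variation between cultures.

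The alternatives tried were scaling by total counts or by DESeq2 1.42.0 size factors, minimums of 20 or 200 reads or none, thresholds of 1.5-fold and 3-fold, no interval condition, a prior count of 5, and leaving out ribosomal protein, mitochondrially encoded and histone genes. Leaving out the MTRNR2L genes and genes with over 1% of a library, and leaving out IMP1 targets shared with the cell cycle, histone and Wnt lists, were added after seeing the data.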

Results

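Total RNA and ribosome-protected fragments were compared between wild-type SW480 cells, an established human colorectal adenocarcinoma line, and SW480 cells labelled as lacking IMP1. IMP1 is the RNA-binding protein encoded by IGF2BP1. The design asks how its loss alters mRNA abundance, ribosome occupancy and their ratio, the translational efficiency. Each of the 4 groups had 1 library, and totals ranged from 3778316 to 5551479 counts. At least 1 read was counted for 14631 genes in wild-type RNA, 14549 in knockout-labelled RNA, 13144 in wild-type RPF and 13236 in knockout-labelled RPF. The most abundant gene in both RNA libraries was PLCG2, with 3.09% of wild-type and 4.63% of knockout-labelled counts. In both RPF libraries it was MTRNR2L12, with 1.55% and 1.58%. The 11 MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA sequence, took 12.4% and 12.1% of RNA counts and 2.90% and 3.60% of RPF counts. No difference below has a replicate check, and genotype cannot be separated from clone or culture with 1 cell population per genotype.

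IGF2BP1 (ENST00000290341, chromosome 17, 48997412 to 49055650, plus strand, GRCh38) did not differ detectably in RNA between the genotypes. It had 598 reads in wild-type RNA and 571 in knockout-labelled RNA, a scaled ratio of 1.06 (95% counting interval 0.944 to 1.19). Its footprints were lower, with 285 reads in wild-type RPF and 149 in knockout-labelled RPF, or 52.3% of wild type (95% interval 42.6 to 63.9). The TE change of IGF2BP1 was −1.02 (−1.35 to −0.69). The paralog IGF2BP2 (chromosome 3, 185643739 to 185825056, minus strand) had RNA and RPF changes of −0.09 and 0.01, with both intervals including no change. IGF2BP3 (chromosome 7, 23310209 to 23470467, minus strand) had an RNA change of −0.41 (−0.68 to −0.15), an RPF change of 0.10 and a TE change of 0.51 (0.15 to 0.86). The IMP1 family list had 0 of 3 members called in RNA, and only IGF2BP1 called in RPF and TE. Counts per gene do not show which exons the IGF2BP1 reads came from, so they do not show a loss of the gene product. Every direction below is therefore between libraries labelled wild type and knockout, and the second is written as knockout-labelled.

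**Figure D1:**
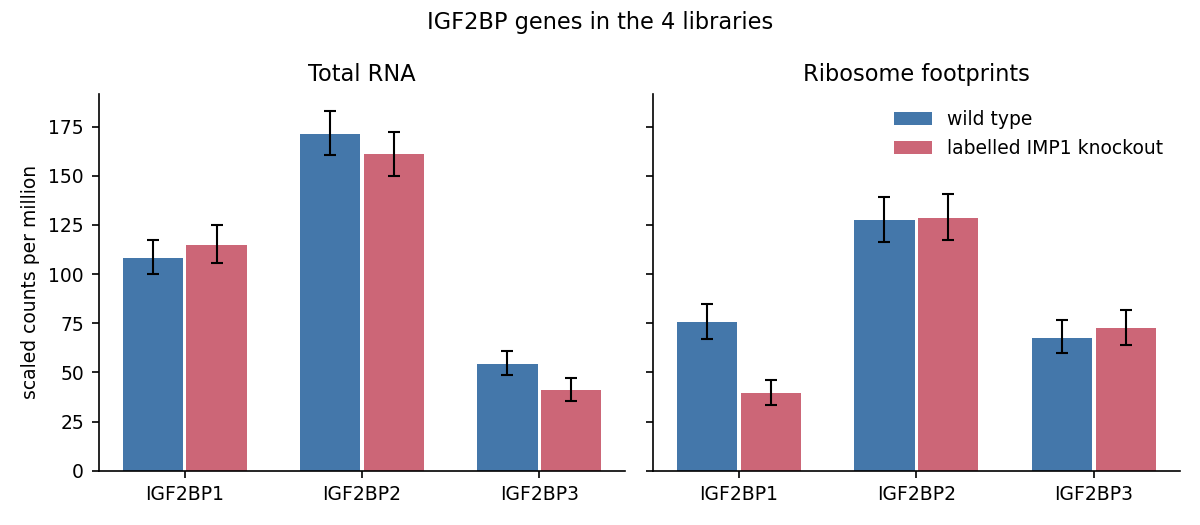
Scaled CPM of IGF2BP1, IGF2BP2 and IGF2BP3 in total RNA (left) and ribosome footprints (right), 1 library per bar, with exact Poisson 95% intervals that cover counting error only. IGF2BP1 stood at 108 and 115 CPM in RNA and at 75.4 and 39.4 in footprints, wild type first.

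In total RNA, genes of the cell cycle, replication-dependent histones and Wnt targets were lower in the knockout-labelled library, and the list medians of endoplasmic reticulum stress, ATF4 and amino acid, and integrin and matrix genes were higher. The Wnt antagonist DKK4 (chromosome 8, 42374068 to 42377232) went from 1325 reads in wild type to 19, which was 61.2-fold lower (log2 −5.94, 95% interval −6.71 to −5.32). IGFBP3, an IGF-binding protein, went from 393 reads to 5, or 64.4-fold lower. The hair keratin KRT81 (chromosome 12, 52285913 to 52291534) went from 374 reads to 5041, or 14.9-fold higher (log2 3.90, 3.75 to 4.06). Of 10875 genes measured, 695 were at least 2-fold higher and 908 at least 2-fold lower in the knockout-labelled library, together 14.7%.

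Among the genes ranked highest in RNA, LCN2, which encodes the siderophore-binding protein lipocalin-2, was 15.2-fold higher (50 and 691 reads) and the uridine phosphorylase UPP1 was 11.7-fold higher (202 and 2138). The cyclooxygenase gene PTGS1 had 8 and 240 reads, the protease gene GZMB 13 and 259, the bradykinin receptor gene BDKRB2 9 and 199, IL20RB 6 and 150, and the calcium channel gene TRPV6 11 and 194, wild type first. SMPD3 had 0 reads in wild type and 74 in the knockout-labelled library, and SPX had 0 and 62. Against the floor of 3 counts they were 27.4-fold and 22.9-fold higher, with exact 95% lower bounds of 21.7-fold and 18.1-fold. KRT83 and KRT86, neighbours of KRT81 with near-identical sequence, had RNA changes of 3.80 and 3.58, so the split of reads among the 3 keratins is uncertain. On the lower side VIL1, encoding the microvillus protein villin, had 160 reads in wild type and 2 in the knockout-labelled library (log2 −5.85, −9.23 to −4.29). ASB4, MYH7B and the Wnt target APCDD1 were lower by 29.6-fold, 18.5-fold and 15.4-fold. The homeobox gene MSX1 had 686 and 44 reads, SLC1A2 182 and 8, NEIL3 102 and 2 (−5.21, −8.59 to −3.63) and ZAP70 123 and 3 (−4.99, −7.50 to −3.62). SOWAHA had 57 and 0 reads and ADAMTS17 56 and 0, 17.1-fold and 16.8-fold lower against the floor.

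Of the 38 G2/M and mitosis genes measured in RNA, 35 were lower and 0 higher, with a list median of −1.24. MKI67, a proliferation marker, was 4.22-fold lower, the survivin gene BIRC5 4.80-fold and the kinetochore gene CENPF 4.06-fold. Among 36 G1/S and replication genes 27 were lower and 1 higher, with a median of −1.08. Thymidylate synthase TYMS was 10.1-fold lower (566 and 50 reads), the helicase subunit MCM5 5.98-fold and the ribonucleotide reductase subunit RRM2 4.17-fold, while the cyclin gene CCNE1 had 13 and 38 reads. All 21 replication-dependent histone genes measured were lower, with a median of −2.47. HIST1H1B went from 996 reads to 89 and HIST1H3H from 1449 to 187, though the histone copies share sequence. In the Wnt target and stem cell list 14 of 19 genes were lower and 1 higher, with a median of −1.41. AXIN2 was 4.06-fold lower, the ubiquitin ligase gene RNF43 4.40-fold, the transcription factor gene SP5 4.49-fold and the Wnt deacylase gene NOTUM 4.10-fold. Each of these 4 medians was below all 10000 matched random lists.

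The endoplasmic reticulum stress list had 15 of 27 genes higher in RNA and 0 lower, with a median of 0.73. The chaperone gene HSPA5 was 2.86-fold higher (1204 and 3103 reads) and the translocon gene SEC61A1 2.22-fold higher, and HERPUD1 had a change of 1.04. ATF4 targets and amino acid genes had 13 of 37 higher and 4 lower, with a median of 0.39. Asparagine synthetase ASNS was 3.28-fold higher and the tryptophanyl-tRNA synthetase WARS 3.19-fold higher, whereas the glutamine transporter SLC1A5 was 3.42-fold lower (6474 and 1704 reads). In the integrins and matrix list 14 of 28 genes were higher and 4 lower, with a median of 0.47. ITGB6 and TNC were 8.47-fold and 3.29-fold higher, and ITGA1 was 5.02-fold lower. Each of these 3 medians was above all 10000 random lists. Autophagy genes had 6 of 36 higher, 3 lower and 27 neither, with a median of 0.32 at percentile 99.9. MAP1LC3B, the LC3B protein of the autophagosome membrane, was 2.02-fold higher, ATG3 and ATG5 had changes of 0.50 (0.25 to 0.75) and 0.41 (0.15 to 0.67), and the receptor gene SQSTM1 had −0.22 (−0.34 to −0.09). Epithelial adhesion and barrier genes went both ways, with 10 of 31 higher, 8 lower and a median of 0.27 at percentile 99.6. E-cadherin CDH1 was 3.81-fold higher and CLDN1 2.80-fold higher, and periplakin PPL was 2.76-fold lower.

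Glycolysis genes had 11 of 22 lower in RNA and 0 higher, with a median of −0.66 below all random lists. Lactate dehydrogenase LDHA was 2.68-fold lower, pyruvate kinase PKM 2.21-fold and GPI had a change of −1.10. IMP1 target transcripts had 6 of 13 lower and 1 higher, with a median of −0.48 at percentile 1.13. Members that are also in the cell cycle or Wnt lists were CD44, LEF1 and MKI67 (4.22-fold lower), and without these the median was −0.42 at percentile 3.56, inside the middle 95%. CTNNB1, encoding beta-catenin, was 2.07-fold lower (3411 and 1481 reads), HMGA2 was 5.04-fold lower, ACTB had a change of −0.72 and CD44 of −0.32, and the ubiquitin ligase subunit BTRC was 2.20-fold higher. Antioxidant and NRF2 genes had 7 of 20 lower and 1 higher, with a median of −0.35 at percentile 2.08. The member that was higher was the ferritin heavy chain FTH1 (15615 and 58044 reads), and NQO1 and GPX4 had changes of −0.76 and −1.07.

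The other lists lay inside the middle 95% of random lists in RNA. Hypoxia genes had 8 of 17 lower and 3 higher, with a median of −0.34 that was −0.71 at a minimum of 20 reads, and EPAS1 was 4.13-fold lower. Inflammatory and NF-kB genes had 9 of 22 higher and 4 lower, with a median of 0.25. LCN2 was the highest of its named members, and the acute phase gene SAA1 was 6.82-fold lower. Interferon response genes had 6 of 25 higher and 6 lower, with a median of 0.05; ISG20 and HLA-B had changes of 2.17 and 1.27 and IFITM2 of −1.23. Immediate early genes had 6 of 28 higher and 2 lower, with a median of 0.09, JUN at 1.23 and DUSP6 at −1.68. Lysosome genes had 4 of 29 higher and 5 lower, with a median of 0.08. Cholesterol synthesis genes had 3 of 28 higher and 4 lower, with a median of −0.21. Heat shock chaperones had 4 of 23 lower and 0 higher, with a median of −0.28, and HSPH1 at −0.67. PI3K and mTOR genes had 3 of 29 higher and 3 lower (median −0.14), and proteasome genes 2 of 31 lower and 0 higher (median −0.11). Respiratory chain genes of the nucleus had 9 of 65 lower and 1 higher (median −0.12), and mitochondrially encoded mRNAs 1 of 13 lower and 0 higher (median −0.17). Cytosolic ribosomal proteins had 75 of 79 neither higher nor lower (median −0.07), and translation factors 37 of 45 (median −0.11). Intestinal differentiation genes were measured for 4 members, of which VIL1 and the transcription factor gene CDX2 were lower (median −0.65). Of the markers of other cell types, 7 mesenchymal genes were measured, of which 3 were lower, FN1 and S100A4 at −1.46 and −1.49 among them, and 1 higher (median −0.44, −0.95 at a minimum of 200 reads). Leukocyte and endothelial markers had 3 measured, with CD68 at 26 and 221 reads and KDR at 1969 and 843 (median 0.15). Neuronal and other lineage markers had 4 measured, with SNAP25 and TUBB3 lower (median −0.53).

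In ribosome footprints, mitochondrially encoded mRNAs were higher in the knockout-labelled library, as were the list medians of ribosomal protein, endoplasmic reticulum stress, and integrin and matrix genes, while cell cycle, histone and Wnt target genes were again lower. KRT81 footprints were 29.1-fold higher (520 and 15170 reads), UPP1 19.6-fold (172 and 3388) and LCN2 17.6-fold (92 and 1633). DKK4 footprints were 101-fold lower (2682 and 26 reads; log2 −6.66, −7.31 to −6.13). VIL1 had 335 footprints in wild type and 0 in the knockout-labelled library, at least 112-fold lower. Of 9794 genes measured, 881 were at least 2-fold higher and 967 at least 2-fold lower, together 18.9%.

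Further genes at the top of the footprint ranking were KRT82 (11 and 376 reads), the lysosomal glycoprotein gene CD68 (4 and 198) and BEX5 (5 and 136), and the keratin-associated genes KRTAP2-4 (1 and 97) and KRTAP2-2 (2 and 87). Ratios rested on few wild-type reads for TEX19, at 1 and 75 (log2 5.65, 3.71 to 11.55). The integrin gene ITGAX had 0 and 55, 18.3-fold higher against the floor, with an exact 95% lower bound of 14.4-fold. Among the lowest, ASB4 was 64.7-fold lower, IGFBP3 62.4-fold, CKMT2 57.5-fold, the prostaglandin dehydrogenase HPGD 24.3-fold, ZAP70 21.7-fold and SAA1 14.7-fold. ANO4 had 77 and 0 footprints and TNFRSF6B 57 and 0, 25.7-fold lower against the floor for ANO4. The glutamate transporter gene SLC1A3 had 81 and 1 footprints (−5.76, −11.66 to −3.82).

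Cytosolic ribosomal proteins had 38 of 79 genes higher in footprints and 1 lower, with a median of 0.55 above all random lists. RPL26 was 3.08-fold higher and RPL19 2.18-fold higher, and RPL23A was the member that was lower, 1.65-fold. Mitochondrially encoded mRNAs had 11 of 12 higher and 0 lower, with a median of 1.75 above all random lists. MT-CYB went from 150 footprints to 817 and MT-CO1 from 1779 to 6113. MT-ND1, the member not called, had 64 and 75, and MT-ND4L, with 32 and 16, fell short of the minimum of 50 reads. Reads of these mRNAs made up 0.0826% of wild-type and 0.290% of knockout-labelled footprints. Endoplasmic reticulum stress genes had 9 of 27 higher and 0 lower (median 0.48, percentile 99.97), ATF4 targets and amino acid genes 14 of 35 higher and 4 lower (0.49), and integrins and matrix genes 13 of 27 higher and 4 lower (0.49, or 0.93 at a minimum of 200 reads). HSPA5 and ASNS were 3.20-fold and 3.35-fold higher. Inflammatory and NF-kB genes had 8 of 20 higher and 3 lower, with a median of 0.47 at percentile 98.8 and the cytokine gene CSF2 9.08-fold higher. Autophagy genes had 9 of 34 higher and 3 lower, with a median of 0.27 at percentile 98.6. MAP1LC3B and PIK3R4 were 2.43-fold and 2.87-fold higher, WDR45B and ULK1 were 2.17-fold and 1.82-fold lower, ATG5 had 0.02 (−0.29 to 0.34) and SQSTM1 −0.15 (−0.28 to −0.03).

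Footprints of G2/M and mitosis genes were lower for 31 of 38 and higher for 0 (median −1.17), and those of G1/S and replication genes lower for 24 of 35 and higher for 1 (median −1.03). All 21 histone genes were lower (median −1.95), as were 12 of 18 Wnt target genes, with 2 higher (median −1.33, or −0.89 with no minimum). These 4 medians were below all random lists. RRM2, CENPF and AXIN2 were 3.63-fold, 3.62-fold and 6.35-fold lower. Glycolysis genes had 8 of 22 lower and 1 higher (median −0.45, percentile 0.080), and hypoxia genes 8 of 18 lower and 1 higher (median −0.58, percentile 0.19), with LDHA and EPAS1 at 2.45-fold and 4.71-fold lower. PI3K and mTOR genes had 6 of 27 lower and 1 higher, with a median of −0.37 that became 0.030 with a minimum of 200 reads; AKT1 had −0.72 and MTOR 0.88. Neuronal and other lineage markers had 2 of 4 higher, SYP (6 and 94 reads) and the muscle gene DES (53 and 164), with a median of 1.11 that was −0.0007 with no minimum. The remaining medians lay within the middle 95% of random lists. They were −0.002 for IMP1 targets (2 of 13 higher, 4 lower), 0.02 for lysosome genes (5 of 29 higher, 2 lower), 0.11 for translation factors (6 of 45 higher, 4 lower) and −0.04 for the nuclear respiratory chain (5 of 65 higher, 7 lower). Epithelial adhesion genes had 0.15 (9 of 29 higher, 5 lower), interferon response genes 0.14 (10 of 27 higher, 4 lower) and immediate early genes 0.24 (7 of 28 higher, 4 lower). For cholesterol synthesis the median was −0.16 (1 of 28 higher, 7 lower), for chaperones −0.10 (3 of 23 higher, 3 lower), for the proteasome −0.01 (0 of 31 higher, 3 lower) and for antioxidant genes −0.25 (0 of 21 higher, 5 lower). Intestinal differentiation genes had −0.14 (1 of 4 lower, 0 higher) and mesenchymal genes 0.11 (3 of 8 higher, 3 lower), which became −0.79 at a minimum of 200 reads. CD68 was the 1 leukocyte marker measured.

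**Figure D2:**
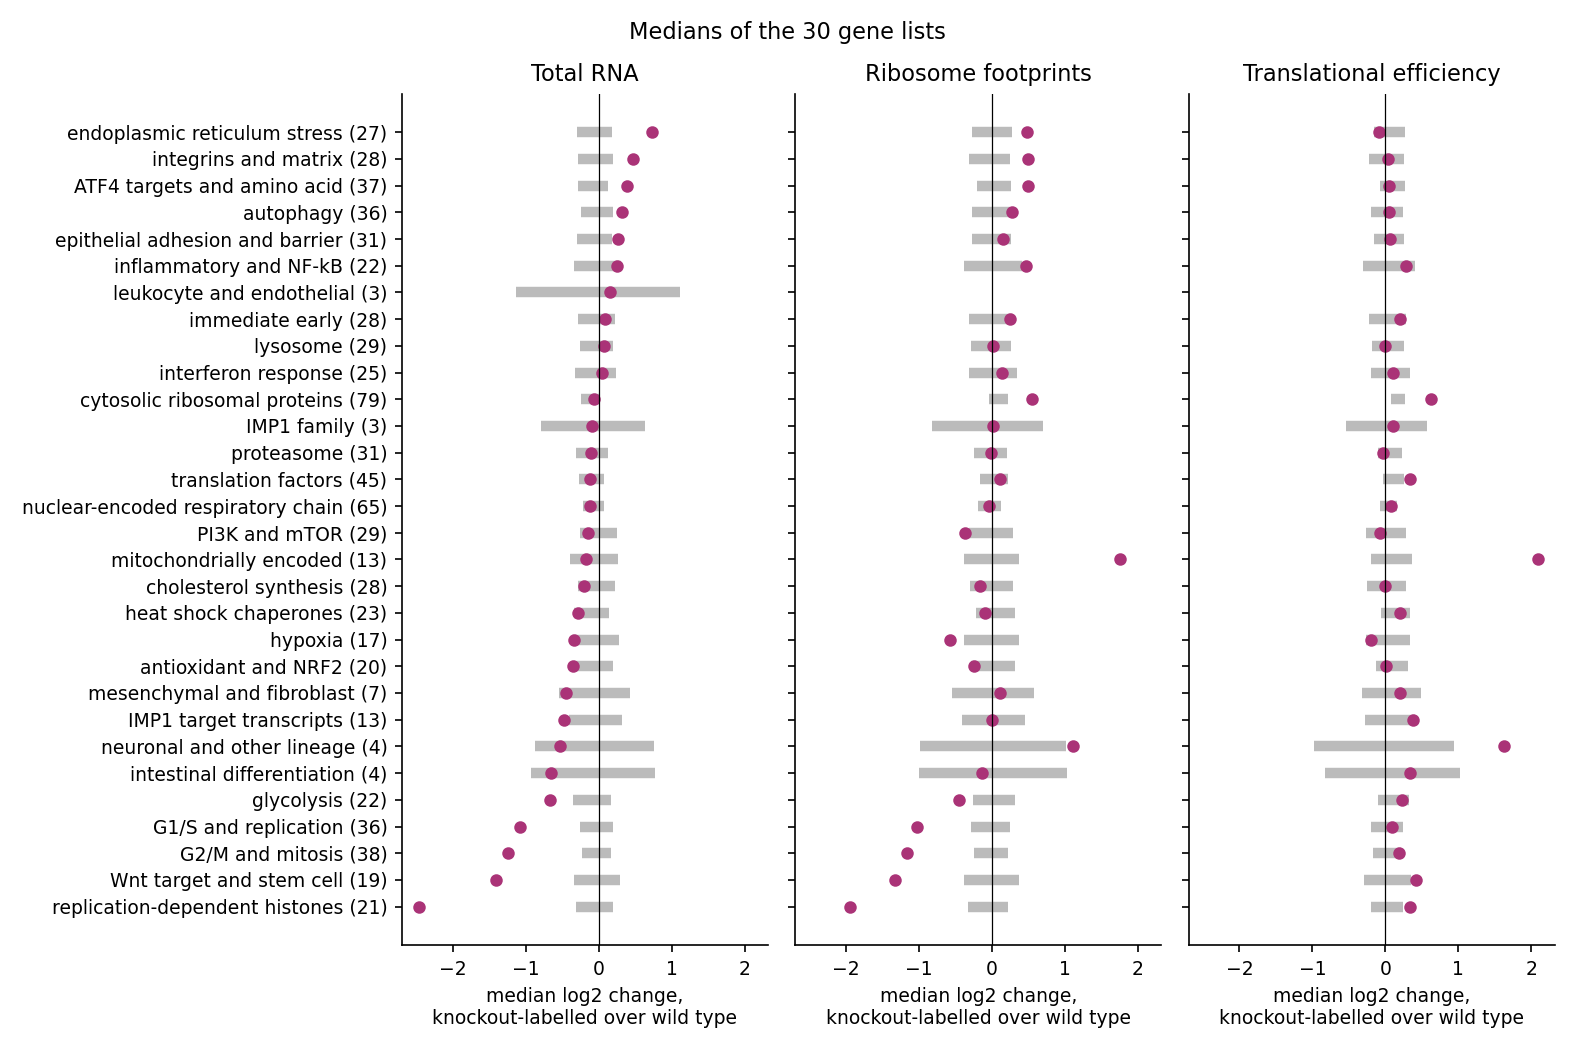
Median log2 change, knockout-labelled over wild type, of each gene list (points) in total RNA, footprints and translational efficiency, with the middle 95% of 10000 matched random lists in grey and the number of genes measured in RNA in brackets. Histones had the lowest RNA median at −2.47, and mitochondrially encoded mRNAs the highest TE median at 2.09.

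RNA and RPF changes went together across the 9598 genes measured in both, with Pearson's r of 0.627 and Spearman's rho of 0.537. In simulated libraries with no effect Pearson's r was 0.003. The sign of the change was the same for 67.8% of genes. KRT81, LCN2 and UPP1 were higher and DKK4, IGFBP3 and VIL1 lower in both measurements. Genes at least 2-fold higher in both numbered 255, against 43.6 for independent lists of the same lengths, and genes lower in both numbered 409, against 73.8.

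**Figure D3:**
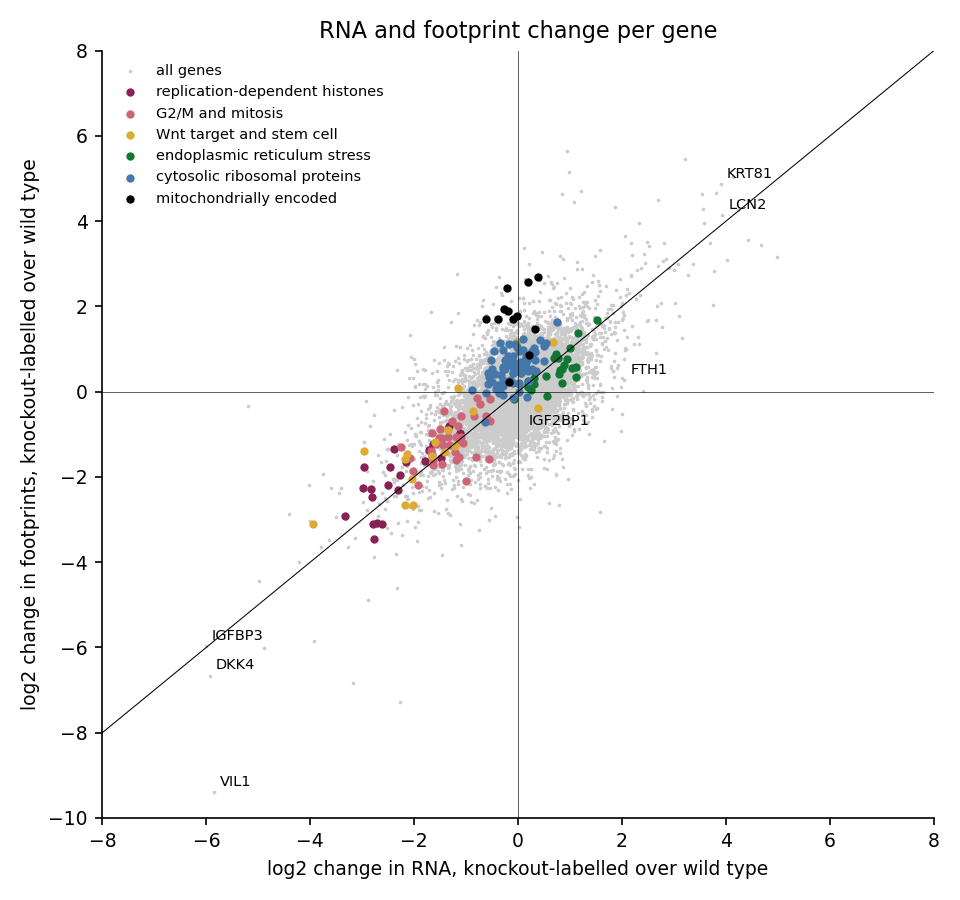
Log2 change in RNA (horizontal) and in footprints (vertical) of 9598 genes, knockout-labelled over wild type, with 6 lists coloured, 7 genes named and a diagonal line for equal change. Mitochondrially encoded mRNAs lie above the line at RNA changes near 0, FTH1 lies below it, and the height of VIL1, with 0 footprints in 1 library, depends on the prior count.

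Translational efficiency was higher in the knockout-labelled libraries for mitochondrially encoded and ribosomal protein mRNAs, and lower for both ferritin subunits. For mitochondrially encoded mRNAs the ratio rests on a small share of footprints, 0.0826% in wild-type and 0.290% in knockout-labelled RPF. Whether their higher ratio reflects translation or a difference in the recovery of these footprints was not tested. The TE of MT-CYB was 6.29-fold higher (log2 2.65, 95% interval 2.40 to 2.91) and that of RPSA, a protein of the small ribosomal subunit, 2.81-fold higher (1.49, 1.40 to 1.58). The TE of FTH1 was 3.44-fold lower (−1.78, −1.85 to −1.72), with RNA 4.13-fold higher and footprints 1.20-fold higher. For the ferritin light chain FTL it was 2.45-fold lower, with RNA at 6425 and 4483 reads and footprints at 623 and 197. Of 9598 genes, 620 had at least 2-fold higher TE and 603 at least 2-fold lower TE.

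Mitochondrially encoded mRNAs had 11 of 12 members with higher TE and 0 lower, with a median of 2.09. MT-ND5, MT-CO2 and MT-CO1 had TE changes of 2.37, 2.08 and 1.80, MT-ND1 had 0.40 (−0.08 to 0.89), and MT-ND4L, below the minimum of reads, had −0.54 (−1.40 to 0.32). Cytosolic ribosomal proteins had 45 of 79 higher and 0 lower, with a median of 0.62, where matched random lists ranged from 0.08 to 0.27 in their middle 95%. RPL41 and RPL19 were 2.67-fold and 2.46-fold higher. Both medians were above all random lists. Translation factors had 10 of 45 higher and 1 lower, with a median of 0.34 at percentile 99.95. The elongation factors EEF1G, EEF2 and EEF1A1 were 1.98-fold, 1.94-fold and 1.71-fold higher, with RNA changes of −0.05, −0.01 and −0.11, and the 4E-binding protein gene EIF4EBP2 was the member with lower TE, at −1.14. Histone genes had 4 of 21 higher and 1 lower (median 0.34, percentile 99.8), and Wnt target genes 6 of 18 higher and 2 lower (median 0.42, percentile 99.1), with LEF1 2.37-fold higher and AXIN2 1.56-fold lower. All 3 neuronal and other lineage markers measured were higher, namely DES, SNAP25 and TUBB3, with a median of 1.62 that was −0.15 with no minimum. IMP1 target transcripts had 3 of 13 higher and 1 lower, with a median of 0.37 at percentile 96.3, inside the middle 95%. IGF2 was 2.25-fold higher, ACTB had 0.43 (0.40 to 0.47), CD44 0.32 and CTNNB1 −0.35 (−0.46 to −0.25).

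Genes at the top of the TE ranking included NEIL3, with footprints at 72 and 57 and few knockout-labelled RNA reads (log2 4.87, 2.99 to 6.75), the actin regulator BRK1 and the ganglioside synthase ST8SIA1 (2.83). ZNF280D, AK7, RFX3, ZBTB46 and KRT10 had TE changes from 2.57 to 3.93. At the bottom were the RNA polymerase III factor BRF2 (−4.40) and the Polycomb gene PCGF6 (−3.43). CCDC109B, CHIC1, ZNF205, ZNF839, TMEM55A, PHACTR2, IFT74, SSBP3 and CASZ1 also ranked among the lowest, with ZNF839 at 58 and 6 footprints and SSBP3 at 191 and 95. Of the 620 genes with higher TE, 403 had footprints at least 1.5-fold higher and 260 had RNA at least 1.5-fold lower. Of the 603 with lower TE, 412 had lower footprints and 225 higher RNA at that threshold. TE and RNA changes share the RNA libraries, and their covariance was −0.153, against −0.0295 in simulated libraries with no effect, while their Pearson correlation was −0.292 against −0.643.

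Autophagy genes had 4 of 34 higher and 5 lower in TE, with a median of 0.05 inside the middle 95%. ATG3 had a TE change of −0.75 (−1.10 to −0.41), ATG5 of −0.38 (−0.78 to 0.02), MAP1LC3B of 0.27 (0.07 to 0.46) and SQSTM1 of 0.06 (−0.11 to 0.23), while ULK1 and WDR45B were 2.34-fold and 2.25-fold lower and ATG4A was 2.16-fold higher. Other medians inside the middle 95% were 0.18 for G2/M genes (5 of 38 higher, 3 lower), 0.09 for G1/S genes (4 of 35 higher, 4 lower), −0.001 for lysosome genes (3 of 28 higher, 0 lower) and 0.08 for the nuclear respiratory chain (9 of 65 higher, 2 lower). Inflammatory genes had 0.27 (5 of 19 higher, 3 lower), interferon genes 0.10 (4 of 25 higher, 0 lower), immediate early genes 0.21 (3 of 27 higher, 3 lower) and glycolysis genes 0.23 (1 of 22 higher, 0 lower). Endoplasmic reticulum stress genes had −0.09 (0 of 27 higher, 3 lower), ATF4 targets 0.05 (3 of 35 higher, 2 lower), chaperones 0.20 (4 of 23 higher, 1 lower) and hypoxia genes −0.19 (0 of 17 higher, 3 lower). PI3K and mTOR genes had −0.07 (1 of 27 higher, 5 lower) with MTOR 2.19-fold higher, integrins and matrix 0.03 (5 of 27 higher, 3 lower), epithelial adhesion 0.06 (3 of 29 higher, 0 lower) with CLDN7 at 1.34, and cholesterol synthesis −0.003 (4 of 28 higher, 3 lower). Proteasome genes had −0.03 with 0 of 31 called, antioxidant genes 0.01 (3 of 20 higher, 2 lower), mesenchymal genes 0.21 with 0 of 6 called and intestinal differentiation genes 0.34 (1 of 4 higher, 0 lower). The leukocyte list had 1 gene measured, CD68, with a TE change of 2.25.

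**Figure D4:**
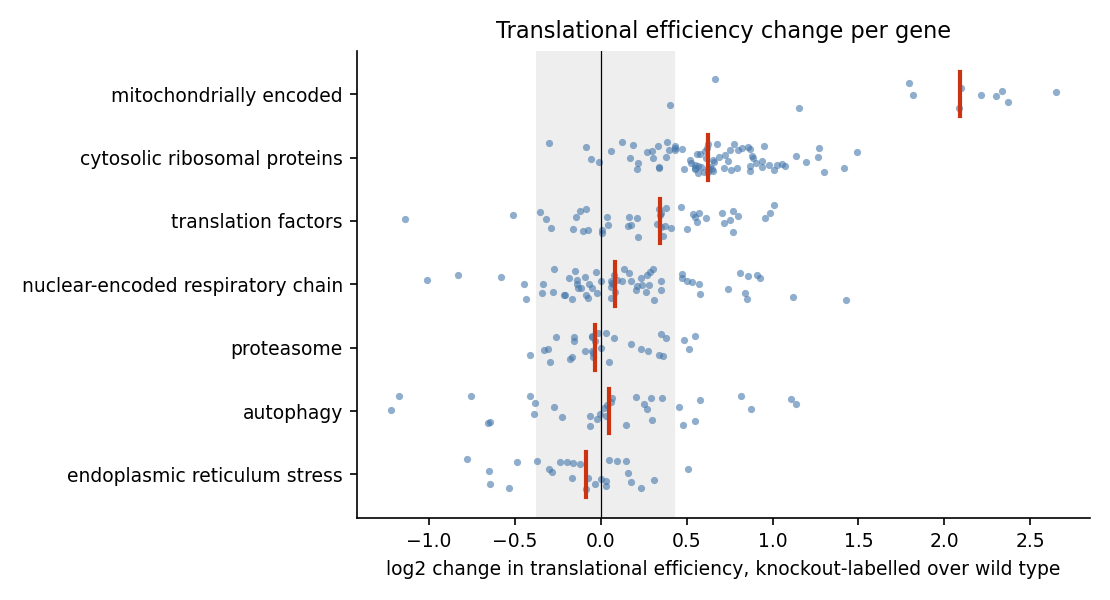
Log2 change in translational efficiency, knockout-labelled over wild type, of each measured gene (points) of 7 lists, with list medians in red and the quartiles of all 9598 genes, −0.37 and 0.42, as a grey band. Mitochondrially encoded mRNAs have a median of 2.09, ribosomal proteins 0.62, and proteasome genes −0.03.

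Within each genotype, footprints were set against RNA reads across different genes. The region of each transcript that was counted is not given, so differences between lists need not be differences in translation. TE relative to the median gene was low for mitochondrially encoded mRNAs, with medians of −5.07 in wild type and −2.91 in the knockout-labelled libraries. For ribosomal proteins the medians were −0.30 and 0.28, at percentiles 0 and 0.090 of random lists of like abundance. PI3K and mTOR genes were low in both (−0.89 and −0.96). Histones (1.27 and 1.47), the nuclear respiratory chain (0.97 and 1.03), the proteasome (1.01 and 1.02), chaperones (1.03 and 1.12) and glycolysis genes (0.84 and 1.02) were high in both, each above the middle 95% of random lists. So were interferon response (0.75 and 0.95), G2/M (0.67 and 0.72) and lysosome genes (0.63 and 0.64).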

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

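The comparison of these counts with independent lists and with simulated libraries was chosen after the counts were seen. Genes whose RNA and footprints went opposite ways stood out because the same contrast moved them in different directions. At a threshold of 1.5-fold with intervals excluding no change, 58 genes were higher in RNA and lower in RPF in the knockout-labelled libraries. Another 58 were lower in RNA and higher in RPF. Examples of the first kind are BRF2 (18 and 49 RNA reads, 74 and 10 footprints, wild type first), the pro-apoptotic gene BID (138 and 197, 458 and 244) and FAM199X (656 and 962, 276 and 171). Examples of the second are BRK1 (214 and 111, 42 and 136), IP6K2 (228 and 113, 89 and 227) and LSM8 (280 and 151, 199 and 299). All except BRF2 and BRK1 were chosen after their values were seen. The most in any of 20 simulated sets with no effect was 1 gene in either direction, while independent lists of the same lengths would share 294 and 314 genes. The simulated sets hold counting error only. Their RNA standard deviation was 0.17 over genes measured in both RNA and RPF, against 0.79 here over the 10875 genes measured in RNA, a wider set. Few genes can reach 1.5-fold in them, so they do not show an excess of opposite changes. At the same threshold 757 genes were higher in both and 915 lower in both, against 274 and 337 for independent lists. The median number of reads over the 4 libraries was 300 for the first kind and 284 for the second. With 1 library per group the difference between RNA and RPF was not tested against replicate variation.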

How the results depend on the processing

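The exclusion of MTRNR2L genes and of genes with over 1% of a library, and that of IMP1 targets shared with the cell cycle and Wnt lists, were chosen after the results were seen. No paired analysis was possible because each group had 1 library. Gene counts moved with the read minimum and the fold threshold, by construction, since these set which genes enter. Genes higher in RNA (695) numbered 306 at a minimum of 200 reads, 1304 with no minimum, 1759 at 1.5-fold and 199 at 3-fold. Genes lower in RNA (908) numbered 501, 1396, 1938 and 316 under the same settings. For RPF the genes higher (881) numbered 368, 1499, 1861 and 290, and the genes lower (967) numbered 470, 1524, 1971 and 340. For TE the genes higher (620) numbered 169, 1079, 1510 and 181, and the genes lower (603) numbered 131, 1059, 1335 and 151. Under the other 7 settings the counts stayed within 1.5 times, at 631 to 973 and 818 to 1142 for RNA, 769 to 1213 and 880 to 1271 for RPF, and 527 to 868 and 521 to 852 for TE. Total or DESeq2 scaling left the share of higher among all calls at 42.4% to 44.8% for RNA, 47.7% for RPF and 48.5% to 52.2% for TE.

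The correlation of RNA and RPF changes (0.627) was 0.559 at a minimum of 20 reads, 0.742 at 200 and 0.273 with none, where genes with few reads entered, and 0.617 to 0.637 otherwise. IGF2BP1 kept its values, at 0.07 to 0.10 in RNA, −0.94 to −0.91 in RPF and −1.04 to −0.999 in TE. Of 691 list medians under alternatives, 20 changed sign, 3 of them from outside the middle 95% of random lists and 17 from inside. Apart from those 3, 682 moved by less than the spread of random lists, which is wide for short lists, and 6 by more. The RPF median of PI3K and mTOR genes was 0.030 at a minimum of 200 reads, and the neuronal list had medians of −0.0007 in RPF and −0.15 in TE with no minimum. With no minimum, the mesenchymal, neuronal and intestinal lists had RNA medians of 0.15, against −0.44, −0.53 and −0.65, and the intestinal list a TE median of −0.15, against 0.34. Most members of these lists have few or no reads, and 0.15 in RNA, −0.0007 in RPF and −0.15 in TE are the values of a gene with 0 reads in both libraries, so medians of such lists with no minimum show no direction. At a minimum of 200 reads the mesenchymal medians were −0.95 in RNA and −0.79 in RPF, against −0.44 and 0.11, and the RPF median of integrins and matrix was 0.93. At a minimum of 20 the leukocyte and endothelial RNA median was −0.46, against 0.15. Different members entered these lists by construction, and beyond that the cause was not tested. The RPF median of Wnt targets was −0.89 with no minimum and the RNA median of hypoxia genes −0.71 at a minimum of 20. Of 6341 values of named genes, 11 moved, and 15 changed sign, none of them called. Depth limits genes near the minimum of 50 reads, whose intervals are wide.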

Other observations

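Chosen only after the results were seen were the scans of symbol stems, of chromosome segments and of footprints per RNA read, the tests of an RNA library distortion and of dividing cells, and the segment tests of GC content or length and of a few genes. Groups of genes that share the letters of their symbol were examined where at least 10 were measured, 120 groups in each comparison, of which 3 would lie on each side outside the middle 95% by chance. In RNA 7 lay below and 7 above, in RPF 7 and 6, and in TE 2 and 7. Several of these stems overlap the fixed lists. They were HIST and MCM below in RNA and RPF, RPL and ATG above in RNA, and RPL, RPS and MT above in RPF. In TE they were HIST, MT, RPL, RPS and EIF above. The remaining TE groups, MRPS and COX above and SNX and CNOT below, were no more than the 3 expected by chance on each side. Genes with the stem RAB, used for small GTPases of membrane traffic but not only for these, had an RNA median of 0.38, with 32 of 43 above 0. Their RPF and TE medians, 0.21 and −0.04, lay inside the middle 95%. TMEM genes, which encode transmembrane proteins, had RNA and RPF medians of 0.27 and 0.32 over 122 genes. SEC genes of the secretory pathway had an RPF median of 0.47, with 20 of 22 above 0. Nucleoporin NUP genes had an RPF median of −0.52, with 19 of 21 below 0, and the splicing factor SRSF genes one of −0.57, with 10 of 11 below 0. MRPS genes of the mitochondrial ribosome had an RNA median of −0.33 and a TE median of 0.30. Its MRPL genes had −0.07 and −0.10, inside the middle 95%, and the difference between MRPS and MRPL genes was not tested. COX genes had a TE median of 0.44 and sorting nexin SNX genes a TE median of −0.41, with 19 of 24 below 0.

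Some genes with many RNA reads had almost no footprints. Over 559 genes with at least 1000 reads in each RNA library, the median was 76.4 footprints per 100 RNA reads. PHACTR1 had 2320 and 3831 RNA reads and 6 and 0 footprints in the wild-type and knockout-labelled libraries. RELN had 1464 and 1281 RNA reads and 6 and 4 footprints, S1PR3 had 3646 and 5235 with 42 and 38, and ZNF844 had 7856 and 14580 with 31 and 147. PLCG2, the gene with the most RNA reads, had 171726 and 228437 RNA reads and 2362 and 2170 footprints. RIMBP3 and RIMBP3B, near-identical copies, had about 1.01 footprints per 100 RNA reads each. MTRNR2L3, a nuclear copy of mitochondrial ribosomal RNA sequence, had 42183 and 42154 RNA reads and 1.05 footprints per 100. The treatment of reads that map to more than 1 gene is not given, so these RNA reads need not come from the named mRNA. No explanation was tested.

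Lower reads of cell cycle, histone and Wnt target genes were weighed first. Intervals here and below, except the exact one, are bootstrap intervals from resampling the genes of a set 2000 times. They take genes as independent, which genes regulated together need not be, and hold no variation between cultures. A distortion of the RNA libraries alone is argued against by the footprints, which come from separate libraries, where the highest of the 4 list medians was −1.03 (bootstrap 95% interval −1.22 to −0.77). GC content or length is argued against by a highest RNA median of −1.14 (−1.28 to −0.88) after the median of genes of like GC content and length was taken off, against −1.08 before. Fewer dividing cells in the knockout-labelled plates may account for the cell cycle and histone lists, whose G1/S and G2/M medians differed by 0.16 (−0.03 to 0.47). This cannot be told apart from an effect of genotype on these genes, since growth of the plates is confounded with genotype in 1 library per group.

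Higher TE of ribosomal protein mRNAs was weighed second. GC content or length is argued against as the whole cause, since the list median was 0.44 (0.38 to 0.56) after correction and 0.62 before, although part of the change was taken off. Most ribosomal protein mRNAs begin with a 5′ TOP motif, through which their translation responds to growth signals. The 17 TOP mRNAs outside the ribosomal proteins had a median TE change of 0.53, with 16 above 0, and 35 other translation factors had 0.22, with 25 above 0. The difference of 0.31 (0.11 to 0.63) only narrowly reached the size set in advance for a change of the TOP class. It was computed without the correction for GC content and length. The RPF medians of these sets were alike, however, at 0.10 and 0.11, with RNA medians of −0.21 and −0.11, whereas ribosomal protein mRNAs had 0.55 in RPF and −0.07 in RNA. A shared change of the TOP class therefore stays a hypothesis, which 1 library per group cannot tie to IMP1.

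Genes at one end of chromosome 4 (1 to 20000000, GRCh38), the lowest of 142 segments of 20 Mb by RNA median, were lower together. The medians over 57 genes were −0.82 in RNA and −0.86 in RPF, with 43 genes below 0 in both. Among these were MSX1 and, named after its values were seen, WFS1, while S100P was higher (34 and 126 RNA reads). Of the 57 genes, 3 are in the fixed lists. GC content or length is argued against by genes elsewhere of like GC content and length. The median change of such genes was taken for each segment gene, and the median of these values was −0.0093 (−0.025 to 0.0084). This interval is a spread of group medians and not of single genes. As for a few genes with large changes, 87.7% of all the segment genes were below 0 in footprints (50 of 57, exact 95% interval 76.3 to 94.9). The lower footprints were thus not limited to a few genes. When genes were shuffled over the segments 1000 times and the lowest by RNA chosen again, that share had a median of 58.6% and a middle 95% that ended at 75%, little below the interval, and no shuffle gave an RNA median below −0.59. The exact interval takes neighbouring genes as independent, which they may not be, so its narrow margin over 75% decides nothing. Both tests replaced first forms that had come out undecided, namely a corrected median of −0.80 (−0.91 to −0.46) against a bound of −0.5 and an RNA median without the lowest 14 genes of −0.49 (−0.77 to −0.28) against −0.3. A further test, of the share below 0 in RNA, was dropped because the choice of the segment by its low RNA median fixes its outcome. A copy number difference between the cells may account for it but cannot be told apart from other causes, since the interquartile range was 1.34 times that of other segments (0.98 to 2.23), which decided neither way, the TE median was −0.21 and no DNA was measured. Outside the middle 95% of random sets lay 22 segments in RNA and 24 in RPF, where 7.1 would by chance, though random sets ignore that neighbouring genes can be related. On the same side in both lay 13 segments, so joint shifts were not particular to chromosome 4. Chromosome 3 (100000001 to 120000000) had medians of 0.54 in RNA and RPF, with 29 of 36 genes above 0 in both. Chromosome 18 (1 to 20000000) had −0.55 and −0.39 over 35 genes.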
